A study of Mus musculus with 6 samples.

How the data were processed

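Total RNA of whole mouse kidneys, 10 ug per sample, was labelled with biotin and hybridised to Affymetrix Mouse Gene 1.0 ST arrays, the array type being given per the file headers. The deposited values were log2 signals per probe set, made by RMA in Affymetrix Expression Console 1.1 per the submitters' processing notes. RMA corrects background, applies quantile normalization across arrays and summarises probes by median polish, so the arrays share nearly the same distribution and a shift of most genes in 1 direction would not be seen. The annotation of the array names the build NCBIM37, which differs from that of the gene table used here, so no coordinates are reported.

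Values came from the value table of 35556 probe sets by 6 samples. Gene symbols and control classes came from the annotation columns of the deposited full RMA table. The plan made before the data were examined had named the signal columns of that full table as the source, with the value table as an alternative. Its 6 signal columns carry array names that match no sample's labels, so they were assigned to no sample and not used, and the planned swap of these files was not run. Of the probe sets, 25004 had 1 gene symbol, 2 had several and 10550 had none, controls included. Symbols of 22271 probe sets were looked up by unversioned accession in RefSeq's gene table for assembly GRCm38.p6, which replaced 2269 old symbols, and the symbol of the file was kept otherwise. The table holds 6559 control and spike probe sets, of which 5222 are negative controls, and these were left out of every test.

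Probe sets with 1 symbol and a log2 signal of at least 5 on at least 3 arrays were kept (20968), and each gene was represented by its probe set of highest mean over all arrays, which left 18238 genes. The median of the negative control probe sets was 5.56 to 5.95 per array and their 90th percentile 7.73 to 7.86, so the filter admitted dim genes, and 10155 of the genes tested (55.7%) lay below that percentile on 4 or more arrays. Differences of dim genes are compressed toward 0 by background. No sequencing depth applies to arrays.

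Groups and replicate numbers were taken per the labels' sample titles, with 3 vehicle and 3 m4PTB samples. The labels number the replicates, and nothing in the sources used here says more than that they are separate samples, so p-values measure the spread between these samples, which may be partly technical. The comparison of m4PTB minus vehicle was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with no covariate, and p-values were adjusted by Benjamini-Hochberg over all genes tested. A gene was called at an adjusted p under 0.05. Single values were also compared by an exact two-sided permutation test, whose smallest p with 3 against 3 samples is 0.1.

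A set of 37 gene lists (974 entries, of which 913 were measured) covered nephron segments, other cell types a kidney can hold, and pathways that fit ischemic injury and an inhibitor of histone deacetylases. Lists with at least 5 measured members were tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the lists, with camera at an estimated correlation and fry beside it. Members were also counted with p-values adjusted over the list alone. The lists, tests, filter, alternatives and the rule for naming genes were chosen before the data were examined. That rule took, in each direction, the 10 genes of largest change among those past the threshold with no overlap between groups, filled up with genes of smallest unadjusted p and no overlap where fewer passed. It passed over loci without a gene name (0 among the higher and 5 among the lower genes), always took Havcr1, Lcn2, H1f0, Cdkn1a, Hdac1, Hdac2 and Hdac3, and took up to 4 members of smallest p per called list and up to 2 of any other list. Not every gene that this rule takes is reported here.

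The steps were tested on data simulated from the means and moderated variances of these genes with normal noise. In 20 simulations of 18238 genes, 73.1% of genes planted with a log2 change of 0.5 were recovered at an adjusted p under 0.05, 99.7% of those with a change of 1 and all of those with a change of 2. The simulated noise was independent between genes and no simulated array stood apart, whereas vehicle replicate 3 did among the real arrays. The shares may therefore overstate what could be recovered here. In the list test, a shift of 0.4 planted in 1 list of independent members was called in 20 of 20 simulations by the preset test and in 20 of 20 with an estimated correlation. In another run the members of each unchanged list shared a random value per array with an SD of 0.3. There the preset camera test called 70.0% of lists, and the test with an estimated correlation called 0 of 740. Calls of lists whose members vary together between animals therefore rest on that choice. Among the real vehicle arrays the list mean had an SD of 0.29 for G2/M and mitosis but 0.05 for the proximal tubule. The 70.0% may therefore overstate false calls for lists that vary less. No shift was planted in a list with a shared value, so the power of the estimated test there is unknown.

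Alternatives were no filter, a filter at a log2 of 6, the mean of a gene's probe sets, every probe set on its own, cyclic loess, subtraction of each array's median, trended and robust variances, array weights, the replicate number as a block, other thresholds, genes of several lists left out, and each array left out in turn. After the data were seen, a filter at the negative controls' 90th percentile and a removal of each array's brightness trend were added. Figures were drawn with matplotlib 3.10.9.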

Results

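Gene expression was measured in injured kidneys of male BALB/c mice aged 10 to 12 weeks, with 1 expression array per sample. A kidney was clamped for 26 min and reperfused, and the opposite kidney was removed. At 24 h after the injury the mice received vehicle, a 20% solution of a cyclodextrin in water, or 100 mg per kg body weight of m4PTB, a compound known as methyl 4-(phenylthio)butanoate and as an inhibitor of histone deacetylases. The kidneys were harvested 12 h later, at day 1.5 after injury. There were 3 vehicle arrays and 3 m4PTB arrays, and their number limits the precision. After the filter on dim probe sets, 18238 genes were compared, all on the deposited log2 scale.

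The series compared m4PTB with vehicle in kidneys of a similar degree of injury, so that differences would reflect the treatment and not the severity of the injury. Kidneys had been selected by 3 criteria, of which Havcr1 (Kim1), a transmembrane protein induced in injured proximal tubules, can be followed on the arrays. Havcr1 signal was 11.71 ± 0.28 (SD, n = 3) in vehicle kidneys and 11.73 ± 0.22 (SD, n = 3) in m4PTB kidneys. The log2 difference was 0.01 with a standard error of 0.16, and the exact two-sided permutation test, whose smallest possible p was 0.1, gave p = 1. Lcn2, which encodes the injury marker NGAL, was at 10.13 ± 0.67 (SD, n = 3) and 10.78 ± 0.42 (SD, n = 3), a difference of 0.66 with a standard error of 0.33 that did not pass limma's test (adjusted p = 0.685). It was 0.27 without vehicle replicate 3 and 0.42 without m4PTB replicate 1.

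Genes of cell division were higher in the m4PTB kidneys than in the vehicle kidneys, and genes of cholesterol and lipid synthesis were lower. All 40 measured genes of the G2/M and mitosis list were higher, with a median log2 difference of 0.65, and all 35 measured genes of the G1/S and DNA replication list were higher, with a median of 0.39. All 27 measured genes of cholesterol and lipid synthesis were lower, with a median of -0.24. Smaller shifts were found in nephron segment lists, which were lower, and in macrophage, matrix and injury lists, which were higher but were not called without vehicle replicate 3. No single gene passed the threshold over all genes tested, and all list calls rested on a preset correlation between genes and were lost when it was estimated (smallest adjusted p = 0.709 with an estimated correlation). The adjustment gave unlike lists this same value. Unadjusted, camera with an estimated correlation gave p = 0.064 for G2/M, 0.096 for G1/S and 0.099 for cholesterol genes. It gave 0.109 for proximal tubule, 0.234 for collecting duct and 0.287 for oxidative phosphorylation genes.

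By limma, 0 of 18238 genes had an adjusted p under 0.05, and 0 had one under 0.10, with a smallest adjusted p of 0.495. At an unadjusted p under 0.05 there were 1318 genes, 852 higher and 466 lower in m4PTB kidneys, where 912 would be found by chance. With each array's median subtracted the split turned to 441 higher and 1064 lower, and the median of all genes moved from 0.01 to -0.05. The 3 m4PTB values lay entirely above or below the 3 vehicle values for 2661 genes, 14.6% of those tested, against the 10% that chance gives, with 1710 higher and 951 lower. Differences were small. Of the genes at an unadjusted p under 0.05, 91 differed by at least 1.5-fold, 89 of them higher and 2 lower. Without m4PTB replicate 1 or m4PTB replicate 2, 835 or 858 genes had an unadjusted p under 0.05.

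The genes of smallest p in the higher direction, none past the threshold, included E2f1, a transcription factor of the G1/S transition, Rad54b, a protein of homologous recombination, and the small GTPase Rac3. E2f1 signal was 7.59 ± 0.15 (SD, n = 3) in vehicle and 8.17 ± 0.09 (SD, n = 3) in m4PTB kidneys, a log2 difference of 0.59 with a standard error of 0.09. Rad54b and Rac3 differed by 0.60 and 0.62. Fgg, the fibrinogen gamma chain, differed by 1.01 with a standard error of 0.15, from 7.23 to 8.24. A set of small nucleolar RNAs, a class of which many but not all members guide the modification of other RNAs, was also among the first 10: Snord73b (0.70), Snord87 (0.77), Snora73a (0.45) and Snora73b (0.46). The last pair are near-identical copies, so their signals cannot be taken as independent. Hcn2, a pacemaker channel, and Lrp11, a member of the LDL receptor family, differed by 0.56 and 0.45. All 10 had an adjusted p of 0.495.

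The genes of smallest p in the lower direction, again none past the threshold, were led by Nat8f1, an N-acetyltransferase-related gene, at 9.49 ± 0.11 (SD, n = 3) in vehicle and 8.92 ± 0.16 (SD, n = 3) in m4PTB kidneys, a log2 difference of -0.57 with a standard error of 0.10. Its paralog Nat8 differed by -0.34, and probes of this family may share target sequence. Cd74, the invariant chain of MHC class II, differed by -0.36, the interferon-induced Oas1a by -0.43, and the endocrine gland peptide Prok1 by -0.34. Abhd14b (-0.39), the Wnt deacylase Notum (-0.34), the cornified envelope gene Lor (-0.43), the surrogate light chain gene Vpreb2 (-0.41) and the olfactory receptor gene Olfr1274 (-0.34) completed the 10. Their adjusted p ranged from 0.547 to 0.587. Notum, which has 2 probe sets, differed by -0.39 to -0.21 over the alternatives in which it was tested. Rac3, Hcn2, Rad54b, Vpreb2, Olfr1274, Lor, Notum and Oas1a lay below the 90th percentile of the negative control probe sets on all 6 arrays.

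**Figure D1:**
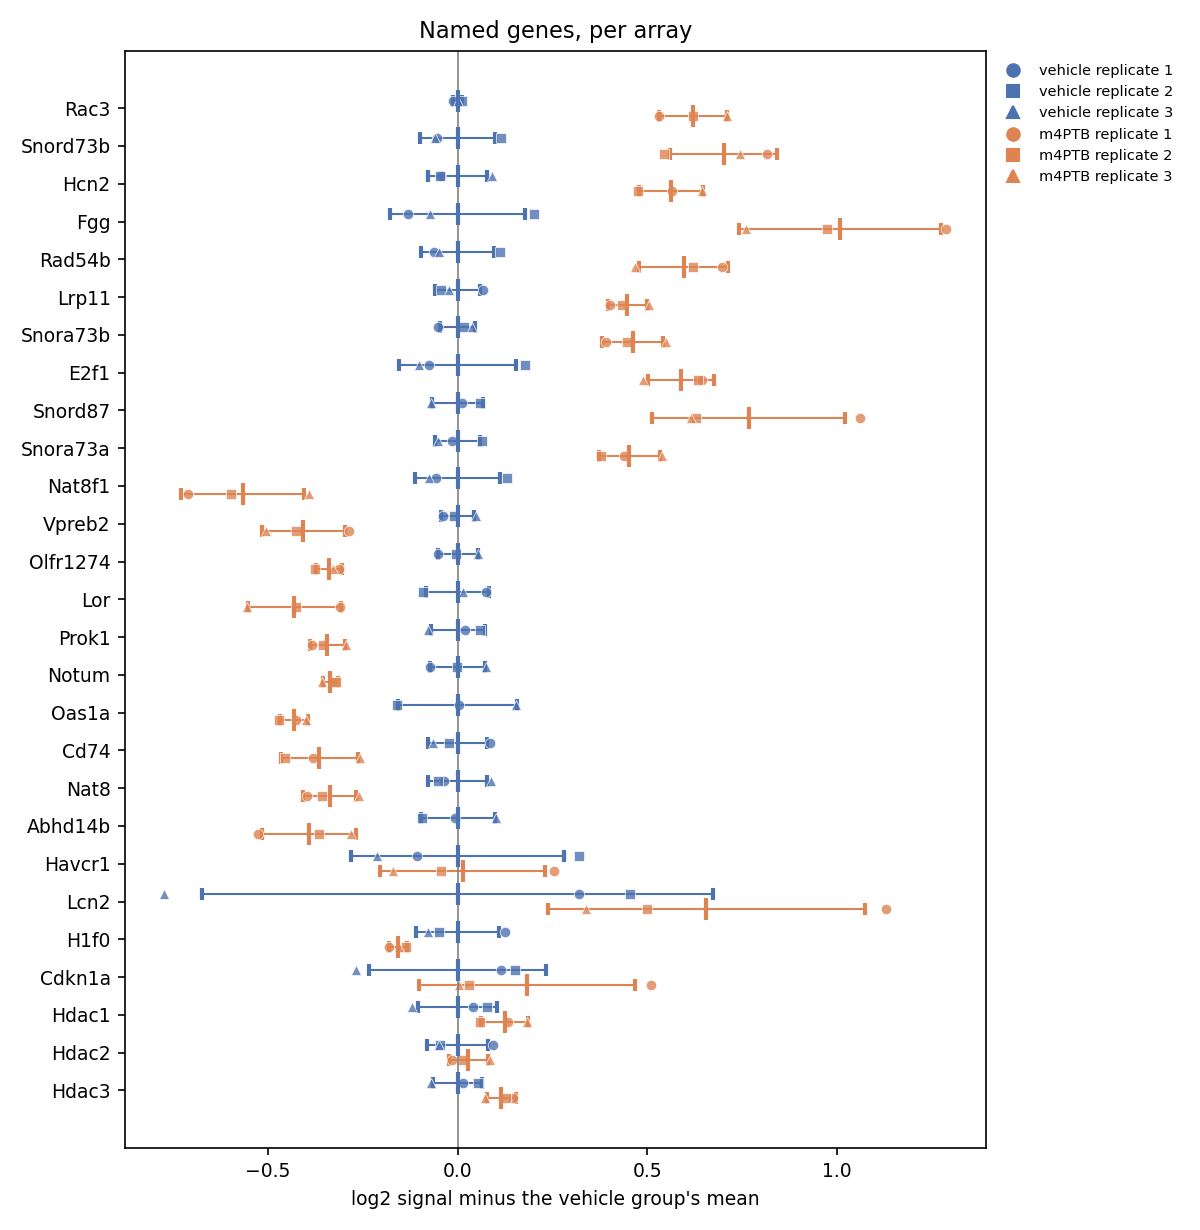
Log2 signal of the named genes on each array, minus the mean of the vehicle group (horizontal axis, log2 units), with vehicle arrays in blue and m4PTB arrays in orange, a marker shape for each replicate, and the group mean ± SD as a bar. The m4PTB arrays lie apart from all vehicle arrays for the 20 genes chosen for that property, while the groups overlap for Havcr1, Lcn2, Cdkn1a, Hdac1 and Hdac2. The groups also lie apart for H1f0, which is lower in m4PTB kidneys, and for Hdac3, which is higher.

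The largest shift of any list was in genes of G2/M and mitosis. The list mean was 7.64 ± 0.29 (SD, n = 3) in vehicle kidneys and 8.26 ± 0.20 (SD, n = 3) in m4PTB kidneys, with every m4PTB array above every vehicle array, and 34 of the 40 genes showed such a separation singly. The means of 6 of the 37 lists separated the groups in this way, where chance gives 10%, and so did 14.6% of all genes tested. Cdk1, the kinase that drives entry into mitosis, differed by 0.86 with a standard error of 0.18, its cyclin partner Ccnb2 by 0.67, the spindle checkpoint kinase Bub1b by 0.66 and the centrosomal kinase Nek2 by 0.78. Of the 40 genes 22 lay above the 90th percentile of the negative controls on at least 3 arrays, and Bub1b did so on none. None of the 40 passed over all genes tested, and 39 passed when adjusted over the list alone. Camera with its preset correlation gave the list an adjusted p of 8.58e-33. The call was lost with the correlation estimated from the arrays (adjusted p = 0.709 with an estimated correlation). Members of this list moved together across arrays, with an estimated correlation of 0.80, which may be only part of the reason. Vehicle replicate 3, which stood apart from the other arrays, had the lowest mean of this list, and without it the median difference was 0.52, 34 members passed when adjusted over the list alone and the adjusted p of the list was 1.32e-29 (adjusted p = 0.944 with an estimated correlation).

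Genes of G1/S and DNA replication differed in the same direction, from a list mean of 7.50 ± 0.24 (SD, n = 3) to 7.90 ± 0.14 (SD, n = 3). The groups were barely apart, with vehicle replicate 2 at 7.767 and m4PTB replicate 3 at 7.770. Besides E2f1, the chromatin assembly factor genes Chaf1a (0.34) and Chaf1b (0.52) and the DNA polymerase alpha gene Pola1 (0.60) had the smallest p. Of the 35 genes 16 lay above the 90th percentile of the negative controls on at least 3 arrays, and Chaf1a and Pola1 did so on none. None of the 35 genes passed over all genes tested, 20 passed when adjusted over the list alone, and 13 separated the groups completely. The preset camera test gave an adjusted p of 6.72e-20 (adjusted p = 0.709 with an estimated correlation). The count of 20 became 2 without vehicle replicate 3 and 0 without vehicle replicate 1, m4PTB replicate 1 or m4PTB replicate 2, but 27 without vehicle replicate 2 and 26 without m4PTB replicate 3. It was 1 with each array's median subtracted and 6 with array weights, and the median difference stayed between 0.32 and 0.55 when any array was left out.

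Genes of cholesterol and lipid synthesis had a list mean of 9.63 ± 0.13 (SD, n = 3) in vehicle kidneys and 9.39 ± 0.13 (SD, n = 3) in m4PTB kidneys, and 12 of the 27 separated the groups completely. The list means were barely apart, with vehicle replicate 2 at 9.488 and m4PTB replicate 3 at 9.480. The sterol oxidase gene Msmo1 differed by -0.47 with a standard error of 0.11, the desaturase gene Scd2 by -0.56, lanosterol synthase (Lss) by -0.35 and squalene synthase (Fdft1) by -0.39. None passed over all genes tested and 0 passed when adjusted over the list alone, where the smallest adjusted p was 0.0523 and 8 genes had an unadjusted p under 0.05. The preset camera test gave an adjusted p of 4.49e-14 (adjusted p = 0.709 with an estimated correlation). The median difference shrank to -0.16 without vehicle replicate 1 and to -0.16 without m4PTB replicate 1. When adjusted over the list alone, 12 genes passed without vehicle replicate 2 and 2 without m4PTB replicate 2, and 4 to 8 passed under 7 of the other settings, among them 6 after cyclic loess, 7 with each array's median subtracted and 8 with trended and robust variances.

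**Figure D2:**
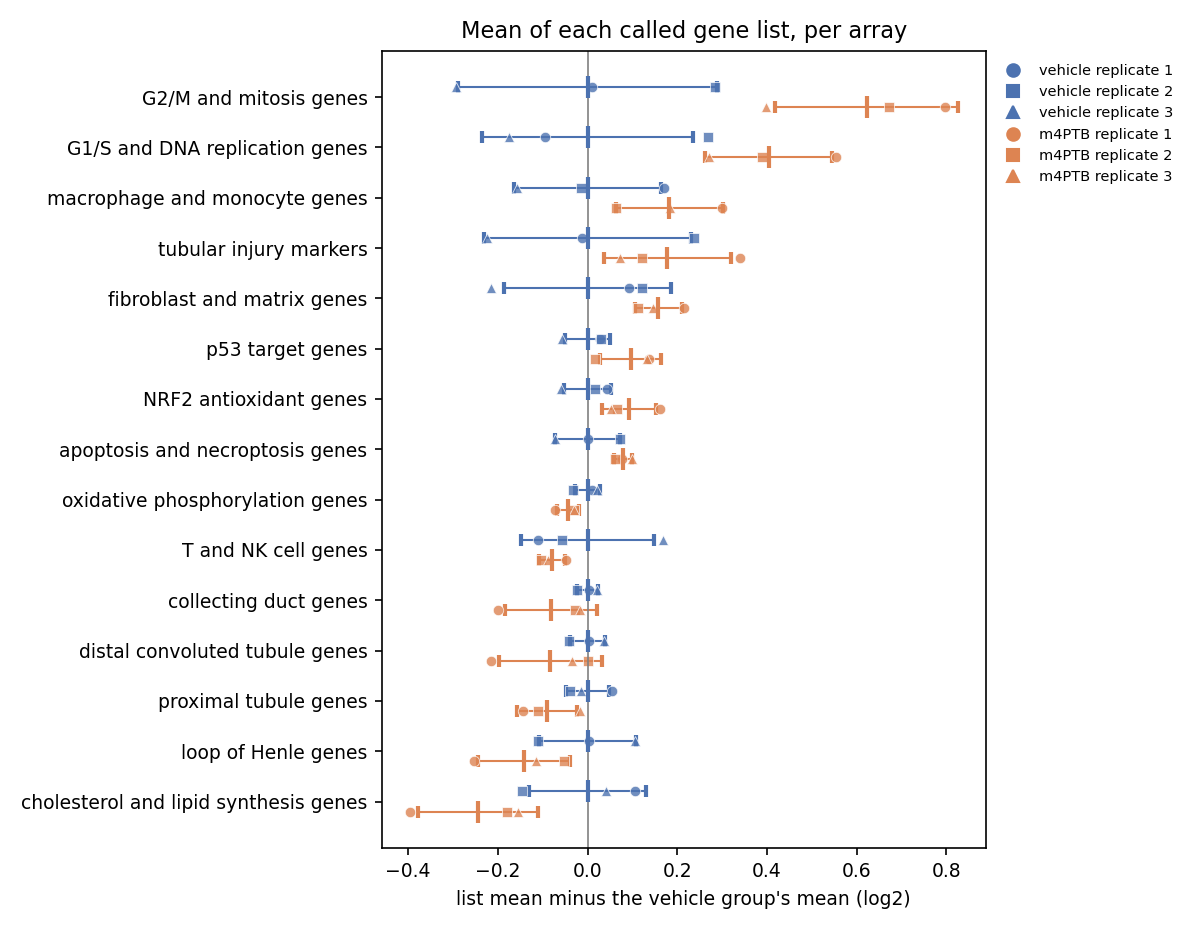
Mean log2 signal of each of the 15 gene lists called by the preset camera test, on each array, minus the mean of the vehicle group (horizontal axis, log2 units), with vehicle arrays in blue, m4PTB arrays in orange and the group mean ± SD as a bar. The m4PTB arrays lie between 0.40 and 0.80 for the G2/M and mitosis genes, above all vehicle arrays, whereas the groups overlap for most of the smaller shifts.

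Genes of the nephron segments were slightly lower in m4PTB kidneys. Of 46 proximal tubule genes 35 were lower, with a median of -0.09, and Slc22a8, an organic anion transporter (-0.32), Hao2 (-0.32) and Miox (-0.24), a renal enzyme of inositol breakdown, had the smallest p. Of 18 loop of Henle genes 17 were lower, with a median of -0.12, among them Sostdc1 (-0.25) and Ppp1r1a (-0.19). Medians were -0.08 over 16 distal convoluted tubule genes, with Fxyd2 at -0.14, -0.09 over 21 collecting duct genes, with the intercalated cell exchanger Slc4a9 at -0.26, and -0.04 over 43 genes of oxidative phosphorylation, with Cox4i1 at -0.24. In each of these 5 lists 0 members passed over all genes tested and 0 when adjusted over the list alone. The preset camera test gave adjusted p from 4.15e-05 to 0.0212, and all 5 calls were lost when the correlation was estimated (adjusted p = 0.709 with an estimated correlation). Without m4PTB replicate 1 the collecting duct median was -0.03, that of the distal convoluted tubule -0.02 and that of oxidative phosphorylation -0.03, and all 3 calls were lost, with adjusted p of 0.399, 0.624 and 0.103. The distal convoluted tubule call was also lost without vehicle replicate 1, with an adjusted p of 0.0819, and with array weights (0.160), and the loop of Henle median became -0.20 without vehicle replicate 2. With each array's median subtracted the medians were -0.15 for the proximal tubule, -0.18 for the loop of Henle, -0.14 for the distal convoluted tubule, -0.14 for the collecting duct and -0.09 for oxidative phosphorylation.

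Macrophage, matrix and injury genes were higher in m4PTB kidneys, and vehicle replicate 3 had the lowest mean of all 3 lists. Over 30 macrophage and monocyte genes the median was 0.14, with the mannose receptor gene Mrc1 at 0.62 and Plac8 at 0.64. Over 29 fibroblast and matrix genes it was 0.17, with Col6a3 at 0.42 and Postn at 0.57 but the proteoglycan gene Dcn at -0.28. Over 25 tubular injury markers it was 0.16, with clusterin (Clu) at 0.59 and Anxa1 at 0.51. Postn and Anxa1 lay above the 90th percentile of the negative controls on no array. In these 3 lists 0 members passed over all genes tested and 0 when adjusted over the list alone. Adjusted p by the preset camera test were 3.46e-04, 0.00287 and 0.0108, and with the correlation estimated the calls were lost (adjusted p = 0.709 with an estimated correlation for the first pair and adjusted p = 0.745 with an estimated correlation for the injury markers). Without vehicle replicate 3 the medians were 0.09, 0.04 and 0.05, and the preset test called none of these lists (adjusted p of 0.107, 0.344 and 0.585). The injury call was also lost without m4PTB replicate 1 (median of 0.11 and adjusted p of 0.284), and the macrophage median was 0.07 without that array. All 3 calls were lost with array weights, and the macrophage and injury calls with the filter at the negative controls' 90th percentile, above which only 7 of the 30 macrophage genes lay, Mrc1 not among them. With each array's median subtracted the medians were 0.09, 0.11 and 0.10.

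A further 4 lists were called by the preset test with medians within 0.10 of 0, and these calls depended on the processing: of the alternatives tested, the call held in 9 of 18 for p53 targets, 12 of 18 for NRF2 genes, 5 of 18 for apoptosis genes and 9 of 16 for T and NK cell genes. Target genes of p53 were higher by a median of 0.09, with Gtse1 (0.27) and Psrc1 (0.33), both also genes of dividing cells, leading the list. NRF2 antioxidant genes were higher by 0.08, with Nqo1 at 0.26 and Hmox1 at 0.44, and apoptosis and necroptosis genes by 0.08, with Ripk3, a kinase of necroptosis, at 0.26. Gtse1, Psrc1 and Ripk3 lay above the 90th percentile of the negative controls on no array. T and NK cell genes were lower by a median of -0.07, with Nkg7 at -0.35, but 0 of the 17 genes lay above the 90th percentile of the negative controls, so this list sat at background. In these 4 lists 0 members passed over all genes tested and 0 when adjusted over the list alone. Adjusted p were 0.0343, 0.0351, 0.0435 and 0.0299 (adjusted p = 0.709 with an estimated correlation for the first 3, and adjusted p = 0.745 with an estimated correlation for T and NK cells). Without vehicle replicate 3 all 4 calls were lost, with medians of 0.04, 0.05, 0.04 and 0.00164 and adjusted p of 0.245, 0.262, 0.499 and 0.816. Without m4PTB replicate 1 the p53, NRF2 and apoptosis calls were lost (adjusted p of 0.103, 0.169 and 0.0636), without m4PTB replicate 3 those of p53 (median of 0.04), apoptosis, and T and NK cells (0.171, 0.171 and 0.0580), and without vehicle replicate 2 those of p53 and NRF2 (0.0620 and 0.0924). The apoptosis call was also lost without vehicle replicate 1 (0.0819) and that of T and NK cells without m4PTB replicate 2 (0.0706). Array weights and cyclic loess ended the p53, apoptosis, and T and NK cell calls, and array weights that of NRF2. With each array's median subtracted the p53, NRF2 and apoptosis medians were 0.03, 0.03 and 0.02, that of T and NK cells was -0.13, and the last pair of calls was lost (adjusted p of 0.0602). The p53 median was 0.15 without m4PTB replicate 2, and that of T and NK cells was -0.11 without vehicle replicate 2.

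Genes known to respond to inhibitors of histone deacetylases did not shift as a group. Over 29 such genes the median was -0.02, with 12 higher and 17 lower, and the preset camera test gave an adjusted p of 0.527 (adjusted p = 0.745 with an estimated correlation). The linker histone gene H1f0, a common marker of exposure to these inhibitors, differed by -0.16 with a standard error of 0.08, and the cell cycle inhibitor gene Cdkn1a by 0.18 with a standard error of 0.16. Every m4PTB value of H1f0 lay below every vehicle value, and the exact permutation test gave its smallest possible p of 0.1. H1f0 differed by -0.09 without vehicle replicate 1, and Cdkn1a by 0.02 without m4PTB replicate 1 and 0.05 without vehicle replicate 3. H1f2 and Fstl3 differed by -0.29 and -0.30. Of 21 genes of histone deacetylases, sirtuins and their cofactors 15 were higher, with a median of 0.03 and an adjusted p of 0.527 (adjusted p = 0.745 with an estimated correlation). Hdac1 differed by 0.12 (0.07 without vehicle replicate 3), Hdac2 by 0.03, Hdac3 by 0.12 and Hdac10 by 0.22. Hdac3 and Hdac10 separated the groups, but Hdac10 lay above the 90th percentile of the negative controls on no array. In both lists 0 members passed over all genes tested and 0 when adjusted over the list alone.

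The other 20 lists were not called, with adjusted p from 0.116 to 0.951 and medians between -0.09 and 0.07. They covered podocytes, endothelium, neutrophils, B cells, erythroid cells, mast cells and platelets, adipocytes, adrenal cortex, muscle, inflammatory cytokines, interferon response, fatty acid oxidation, the unfolded protein response, heat shock, immediate early genes, hypoxia and glycolysis, kidney development, retinoic acid signalling, TGF-beta and BMP targets, and complement and coagulation. Members that passed when adjusted over the list alone were Fgg of the coagulation list, Aldh1a1, a retinaldehyde dehydrogenase (0.61), of the retinoic acid list, and Oas1a of the interferon list, 1 in each, against 0 over all genes tested. Serpina3n, an acute phase gene of the same list as Fgg, differed by 0.76, Rarres1 by 0.47, Pecam1, an endothelial adhesion gene, by 0.35, and the growth factor gene Lif by 0.25. Rarres1 and Lif lay above the 90th percentile of the negative controls on no array. In all, the preset test called 15 of 37 lists, 8 higher and 7 lower, whereas camera with an estimated correlation called 0 and fry called 0, with 1 list, G2/M and mitosis, at an unadjusted fry p under 0.05. Without vehicle replicate 3, or without m4PTB replicate 1, 8 lists were called.

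Vehicle replicate 3 stood apart from the other 5 arrays. Its mean correlation with the others over the genes tested was 0.987, against 0.993 to 0.994 for the rest, and the first principal component, with 50.1% of the variance, separated it from them. Its deviations fell with the brightness of a gene (Spearman correlation of -0.48 across genes, which are not independent replicates, against -0.03 to 0.30 on the other arrays). The 287 olfactory receptor genes tested lay 0.24 above their mean over all arrays there, against -0.08 to 0.00 elsewhere. Its weight by limma's array weights was 0.242, against 0.834 to 2.46 for the others.

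**Figure D3:**
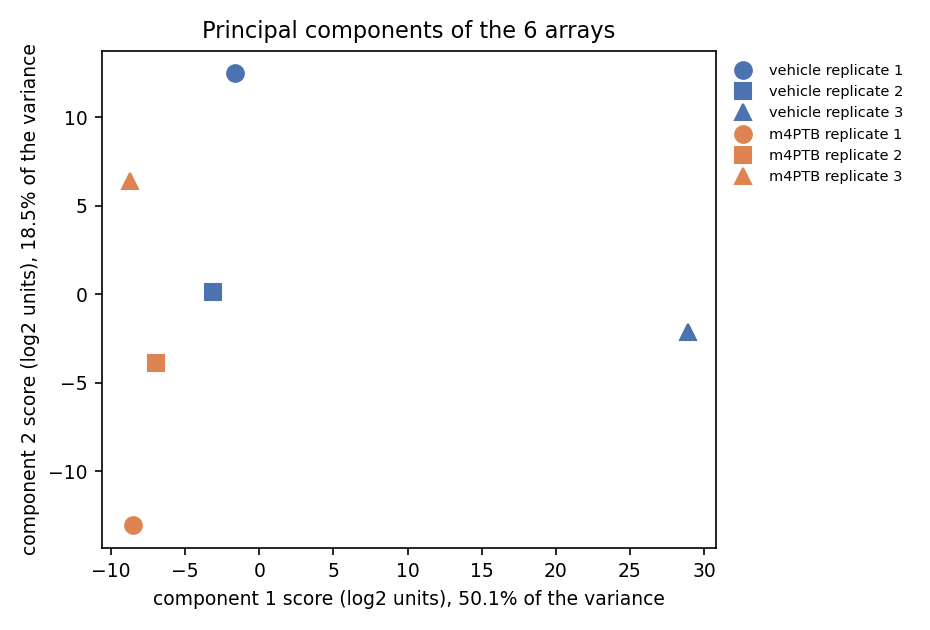
Scores of the 6 arrays on the first 2 principal components of the 18238 genes tested (axes in log2 units, with 50.1% and 18.5% of the variance), with vehicle arrays in blue and m4PTB arrays in orange. Vehicle replicate 3 lies at 28.9 on the first component and the other 5 arrays lie between -8.70 and -1.60.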

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

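Limma called 0 genes at an adjusted p under 0.05 under each of the 17 other settings of values or samples, where the smallest adjusted p ranged from 0.104 to 0.888, and 0 at an adjusted p under 0.10 or with a 1.5-fold minimum. The count at an unadjusted p under 0.05 was 1318, and 772 with the filter at the negative controls' 90th percentile (chosen after the data were seen), which tested fewer genes (8083). It ranged from 835 to 1810 with an array left out. Subtracting each array's median turned its split to 441 higher and 1064 lower, and removing the brightness trend to 783 and 738. Of the 27 genes named outside the lists, all but Havcr1 and Hdac2 kept their direction wherever they were tested, and list members were not followed singly.

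The preset camera test called 15 lists, and 8 with array weights, 9 with the filter at the negative controls' 90th percentile, 0 with an estimated correlation and 0 with fry. With an array left out the count ranged from 8 to 17. The cause of these changes was not tested, except that the stricter filter left 30 lists to test. Lists called in all 18 alternatives that kept the preset test were G2/M and mitosis, G1/S and DNA replication, cholesterol and lipid synthesis, loop of Henle and proximal tubule. Of the 15 called lists 14 kept the sign of their median throughout. The median of T and NK cell genes ranged from -0.11 to 0.00164 with an array left out. Of the 22 lists not called 20 changed the sign of their median somewhere and none was called in more than 2 alternatives. After these sign changes were seen, list directions were taken from the median and not from the test, and of the uncalled lists only those on histone deacetylases are given singly here.

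Havcr1 differed by -0.0434 with each array's median subtracted, by -0.13 with array weights, and from -0.11 to 0.17 with an array left out. Hdac2 differed by -0.0205 after cyclic loess, -0.0286 after median subtraction and -0.0195 with the brightness trend removed, and from -1.24e-04 to 0.0757 with an array left out. The HDAC inhibitor list had medians of 0.0107 with array weights, 0.0316 with the filter at the negative controls' 90th percentile, and -0.0480 to 0.0310 with an array left out. The list of histone deacetylases and sirtuins had -0.00699 after cyclic loess, -0.0269 after median subtraction, -0.00864 with the brightness trend removed, and -0.00173 to 0.0736 with an array left out. The cause was not tested.

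No pairing by replicate number was seen in the values. Same-numbered arrays correlated at -0.13, -0.05 and -0.08 in their deviations from the group means, and other pairs at -0.04 to 0.15. With 3 arrays per group these correlations cannot show whether the numbers pair the animals. With the replicate block, 0 genes were called, 1105 had an unadjusted p under 0.05 and 15 lists were called. The smallest adjusted p by limma was 0.235 with the block and 0.495 without it. Signal over background limits the test, since 55.7% of the genes tested lay below the negative controls' 90th percentile on 4 or more arrays. The planned swap of files was not run, because the 6 signal columns of the full table match no sample's labels.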

Other observations

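The gene families and process terms, their definitions, the follow-up tests of each pattern and the split tests were chosen after the data were seen, whereas the G2/M and cholesterol lists, the estimated correlation and the omission of single arrays had been fixed before, and the tests against random lists and of the brightness trend were written before their own values were seen but after list results with the trend removed had been. Small nucleolar RNA genes were higher in m4PTB kidneys. Of 36 box C/D genes 31 were higher, with a median log2 difference of 0.15, and Snord52 (0.39), Snord49a (0.41) and Snord35b (0.26) separated the groups beside Snord73b and Snord87. Of 25 box H/ACA genes 24 were higher, with a median of 0.22, among them Snora16a (0.47). Histone genes of the chromosomal clusters, whose copies are close in sequence, had a median of 0.28 over 57 genes, 52 of them higher, but none separated the groups. This set had been narrowed after a first look at 77 histone genes with a median of 0.20, 58 of them higher and 19 lower. For the wider set the preset camera test gave an adjusted p of 8.04e-06 (adjusted p = 0.482 with an estimated correlation). That first look covered 9 families by name, MHC class II not among them, and ribosomal protein genes (median of 0.04), microRNA genes (-0.05), vomeronasal receptor genes (-0.03) and predicted genes (-0.06) were not followed up. The preset camera test also called ribosomal protein, microRNA and predicted genes (adjusted p of 0.0341, 1.64e-04 and 5.79e-05). These calls were lost with an estimated correlation (adjusted p of 0.657, 0.482 and 0.482) and without vehicle replicate 3 (adjusted p of 0.759, 0.161 and 0.287). MHC class II genes were lower, 10 of 11 with a median of -0.18, with H2-Aa at -0.37 and H2-Eb1 at -0.32 beside Cd74. Camera with its preset correlation, adjusted over 5 families with the olfactory receptor genes, gave these families adjusted p of 2.17e-07, 2.72e-08, 9.66e-08 and 1.49e-06. All 4 calls were lost when the correlation was estimated (adjusted p = 0.140, 0.170, 0.408 and 0.140 with an estimated correlation). Adjusted together with the families of the first look, the latter values were 0.243, 0.265, 0.482 and 0.243. The small nucleolar RNA and MHC class II sets hold genes already named for their small p, so these p-values are no separate support. Without vehicle replicate 3 the medians were 0.14, 0.26, 0.17 and -0.14, and their signs were the same under all 3 other scalings. With each array's median subtracted they were 0.09, 0.16, 0.23 and -0.24. The 287 olfactory receptor genes had a median of -0.08 (adjusted p = 3.16e-07, adjusted p = 0.408 with an estimated correlation), which was 0.01 without vehicle replicate 3 (adjusted p = 0.879).

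Of 882 process terms in the deposited annotation, the preset test called 45, 31 higher and 14 lower, and 0 with an estimated correlation (smallest adjusted p = 0.934). The higher terms were led by mitosis (191 genes, median of 0.16) and DNA replication (108 genes, 0.18), and included RNA splicing (184 genes, 0.09) and ribosome biogenesis (50 genes, 0.10). The lower terms included cholesterol biosynthesis (24 genes, -0.15) and proton transport (71 genes, -0.06). Without vehicle replicate 3, 25 terms were called, 23 of them shared and in the same direction, and ribosome biogenesis was not among them (adjusted p = 0.807). The highest count in the other splits of the arrays was 47 terms. Of 5 genes that differed by at least 2-fold, Car3, a carbonic anhydrase of muscle and fat, differed by 1.04, Arhgap11a, a gene of dividing cells, by 1.04 and Fgg by 1.01, whereas the milk protein genes Csn3 (-1.44) and Wfdc18 (-1.02) had standard errors of 0.93 and 0.71. The other fibrinogen chains Fga and Fgb differed by 0.36 and 0.28. Their vehicle means of 5.95 and 5.90 were close to the negative control medians of 5.56 to 5.95, and Fgb did not separate the groups.

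The higher cell cycle genes are the pattern most worth following up. Vehicle replicate 3 alone does not account for it, since the median of the G2/M list was still 0.52 without that array, and neither does the brightness of these genes, since the median lay above 100% of 10000 random lists of the same size and mean expression. A candidate explanation left open is that the m4PTB kidneys were more severely injured or at another stage of repair: Lcn2 (0.66), Clu (0.59) and the injury list (median of 0.16) were higher, though Lcn2 was at 0.27 and the list's median at 0.05 without vehicle replicate 3, while Havcr1 differed by 0.0138 with a standard error of 0.16 and was a criterion of selection, so its balance was partly set by design. These cannot be told apart here from an effect of m4PTB itself. The 6 arrays make 10 splits, too few for a share under 0.05, and the real split gave the list a p of 2.32e-34 (1 of 10 splits reached it) against 2.53e-28 for the next, of vehicle replicates 1 and 3 with m4PTB replicate 3 against the rest, while the G1/S list had 3.63e-21 against a smaller 6.78e-27 in another split.

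The lower cholesterol genes may follow single arrays in part, as the median went from -0.24 to -0.16 without m4PTB replicate 1 and also to -0.16 without vehicle replicate 1, but m4PTB replicate 1 alone does not account for the pattern. Brightness does not either, as the median lay below 100% of the random lists. The real split gave a p of 3.64e-15, and the split of vehicle replicates 1 and 3 with m4PTB replicate 3 against the rest gave 3.43e-15, so 2 of 10 splits reached it. Over all genes, all 10 splits gave 0 genes at an adjusted p under 0.05, and the real split gave 1318 at an unadjusted p under 0.05 against at most 959 in the others (1 of 10). Counting the real split, 2 of 10 splits called at least the 15 lists that it called, the highest other count being 16. For 14 of these 15 lists another split gave a p as small.

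Vehicle replicate 3 differed from the other arrays in a way that no label explains. A raised background was not seen in its negative control probe sets, whose median of 5.56 lay below the 5.88 to 5.95 of the other arrays. Its olfactory receptor genes were brighter, however. All these values followed background correction and quantile normalization, so they cannot decide whether the raw background of that array was raised. Its G2/M mean was 0.44 below that of the other vehicle arrays, which differed from each other by 0.27, and 88.2% of that gap was left with the brightness trend removed. The trend may therefore be a separate matter from its low cell cycle genes, and a milder injury or a slower repair in that kidney was not tested.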
